A study of Rattus norvegicus with 35 samples.

How the data were processed

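Liver small RNA was measured in 35 samples from rats given ketoconazole at 3 doses or its vehicle for 3 durations. Per the labels' protocols, total RNA was extracted with RNeasy Plus Universal Mini kits and small RNA libraries were made with Illumina TruSeq Small RNA kits. The deposited table holds raw read counts per mature miRNA, made by the authors, for 763 rat miRNAs in 37 count columns, with no normalization. Per the submitters' processing notes the genome build was rn6. The aligner, the counting program and the miRNA annotation release are not given in the sources used here, nor is how reads that fit several miRNAs or precursor copies were assigned. Counts of near-identical miRNAs are therefore uncertain: miR-466b-2-3p and miR-466b-4-3p hold the same counts and are named once. No genome coordinates are given because the gene table at hand belongs to another assembly.

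Each column was assigned to a sample by its name. Middle dose day 14 replicates 2 and 3 had 2 columns each, taken as repeat runs and summed to 1 replicate each. Replicates of one group differed by more than counting noise: the chi-square per degree of freedom, over miRNAs with a summed count of at least 20, had a median of 92.7 over 34 pairs and a minimum of 34.8, against 8.09 and 5.74 between the 2 runs of replicates 2 and 3, so no library was taken as deposited more than once.

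Of the 763 miRNAs, 151 had 0 counts in all libraries. The filter filterByExpr with the groups (minimum count 10, minimum total count 15) kept 328. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with 1 mean per group over all 35 libraries, leaving 23 residual degrees of freedom, robust quasi-likelihood dispersions and the quasi-likelihood F-test. p-values were adjusted by Benjamini-Hochberg within each comparison and the threshold was an adjusted p of 0.05. The standard error is the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM for principal components has a prior count of 2. Intervals on shares of hairpins are exact binomial intervals at 95%. Reads carry no stated molecular identifiers.

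There were 17 planned comparisons: each dose with the control of its day, the average of each dose over days, the trend over dose steps, the high dose effect on day 7 or 14 minus day 3, and controls of days 7 and 14 with day 3. Another 7 comparisons were added after the data were examined. miRNAs were named by a rule set before the data were examined. It takes the largest changes each way among miRNAs past the threshold with a mean CPM of at least 10. Their treated libraries must all lie on one side of the matched control mean. The limits were 8 each way for the high dose on each day, 12 for its average and 4 in the other planned comparisons. The rule as first set did not cover the 7 added comparisons. It was applied to them after the data were examined, with the compared group in place of the control. The limits there were 8 each way for the high against the middle dose and for the high against the low dose on day 7, and 4 for the others. Interactions and the trend did not need the condition on single libraries. Where none passed, the 3 smallest p values are named. Neither these miRNAs nor the list members had to reach the minimum CPM, and miR-34c-3p, for one, had a mean of 1.1 CPM. The rule adds up to 4 members of each of 16 lists and 5 miRNAs that are always reported: miR-122-5p, miR-192-5p, miR-34a-5p, miR-21-5p and miR-331-3p. Other named miRNAs, including miR-100-5p, miR-99b-5p and let-7e-5p between the high and middle doses and the arms in the hairpin comparison, were chosen after their values were seen. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, 12 of the 16 having the 3 tested members this needs; an estimated correlation and fry were alternatives.

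Alternatives were DESeq2's size factors, library size alone, no low-count filter, a filter of CPM of at least 10 in at least 3 libraries, DESeq2 1.42.0, only the libraries of the days compared, the replicate number within day as a block, and each library left out in turn. Added after the data were examined were thinning to one depth, either run alone of the repeated libraries, and averages without day 7. The steps were tested on simulated counts with the measured means, library sizes and dispersions of the 328 miRNAs, 200 of them changed. For the high dose average, 78% of 1.5-fold and 97% of 2-fold changes were recovered, with 4 calls among the 128 unchanged miRNAs. For the high dose on day 14, with 2 controls, the shares were 29% and 85%. For the high against the middle dose 84% and 96% were recovered, with 8 calls among the 128. Figures were drawn with matplotlib 3.10.9.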

Results

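MicroRNAs (miRNAs), the short RNAs that repress messenger RNAs, were counted by small RNA sequencing in the livers of male Sprague-Dawley rats, 6 weeks old, dosed by mouth with ketoconazole. Ketoconazole is an azole antifungal drug that blocks sterol synthesis in fungi and is known to injure the liver in some patients. The study asked which liver miRNAs change with the dose and duration of treatment, as candidate markers of liver injury. Doses were 10, 30 and 100 mg/kg per day (low, middle and high), controls received 0.5% methylcellulose, and livers were taken 24 h after the last of 3, 7 or 14 days of dosing. There were 3 samples in each of the 12 groups except control day 14, which had 2, giving 35 libraries. Total counts per library ran from 2665943 to 9665416, with a median of 3758063. The highest totals belonged to middle dose day 14 replicates 2 and 3, whose 2 runs were summed. The labels number the replicates within a group without saying that each is a separate rat, so the p-values measure the spread between these samples. The most abundant miRNAs were miR-22-3p, at a mean of 17.95% of the counts, miR-192-5p, at 17.28%, and miR-21-5p, at 6.4%.

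Before any test, the libraries formed 2 clusters that did not follow the dose steps. The first principal component of log2 CPM carried 46.2% of the variance. The 14 libraries of the controls and of the low dose on days 3 and 14 scored between -14.49 and -4.32. The 21 libraries of the low dose on day 7 and of the middle and high doses on all days scored between 4.24 and 6.47. No group had libraries on both sides. Among the controls, day 7 replicates 2 and 3 lay farthest out, at -14.49 and -13.26, against -7.47 for replicate 1. Every comparison of the middle or high dose with control, and of the low dose with control on day 7, therefore also compares the 2 clusters. The labels name no library or sequencing batch, so no value within a batch can be given for these comparisons.

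**Figure D1:**
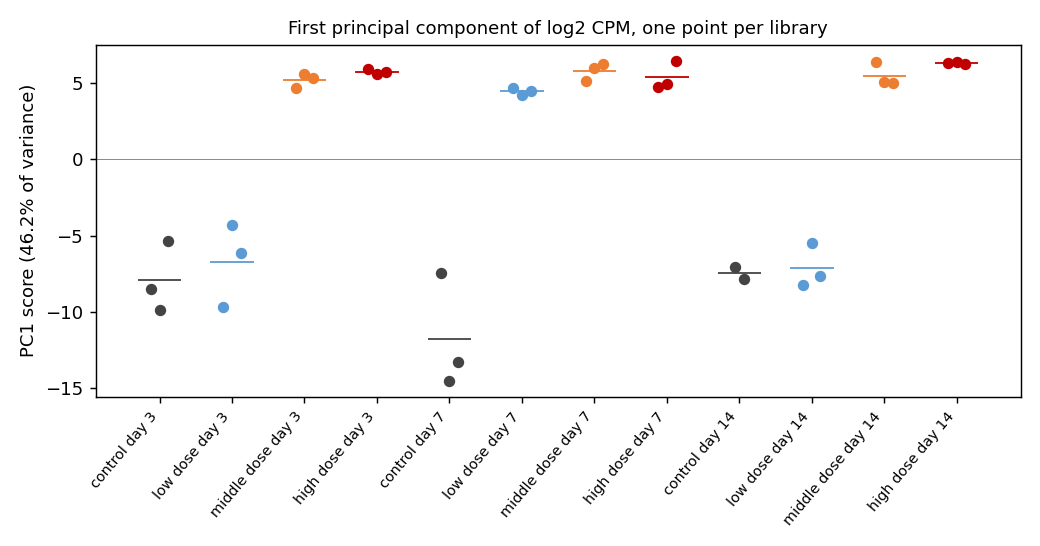
Score of each of the 35 libraries (points) on the first principal component of log2 CPM (vertical axis, 46.2% of the variance) by group (horizontal axis), with a line at the group mean. Scores lie between -14.49 and -4.32 for the controls and the low dose on days 3 and 14, and between 4.24 and 6.47 for all other groups.

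At the high dose, averaged over the 3 days, miR-22-5p rose most among the miRNAs the naming rule selects, by 4.19 ± 0.16 (log2 fold change ± SE, 9 high dose against 8 control libraries), an 18.2-fold rise. miR-22-3p, the other product of its hairpin and far more abundant (means of 181095.5 against 121.5 CPM), rose by 0.46 ± 0.06. Under the rule, miR-22-5p was followed by miR-128-3p at 3.93 ± 0.23, miR-671 at 3.09 ± 0.19, miR-322-3p at 2.82 ± 0.12, miR-222-3p at 2.60 ± 0.18 and miR-28-3p at 2.58 ± 0.12. The abundant miR-191a-5p rose 5.7-fold, by 2.51 ± 0.11 on the log2 scale. miR-423-3p, miR-193b-3p, miR-145-5p, miR-423-5p and miR-203b-3p rose by between 2.32 and 1.95. The largest falls under the same rule were those of miR-363-3p at -1.52 ± 0.15, miR-99a-5p at -1.29 ± 0.13, miR-24-2-5p at -1.21 ± 0.11, miR-141-3p at -1.17 ± 0.19, miR-125b-5p at -1.08 ± 0.10 and miR-16-5p at -1.04 ± 0.09. They were followed by miR-466c-5p, miR-130b-3p, miR-466b-2-3p, miR-214-3p and miR-144-3p, which fell by 0.99 to 0.91 on the log2 scale. The rule itself required each of the 9 high dose libraries to lie on the same side of the matched control mean for these miRNAs. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 206 of the 328 miRNAs tested passed an adjusted p of 0.05, 103 higher and 103 lower, and 59 of them changed at least 2-fold. The adjusted p was 5.31e-20 for miR-22-5p and 4.27e-10 for miR-363-3p.

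On single days the same leaders appeared at the high dose. miR-22-5p was higher by 4.21 ± 0.26 on day 3, 4.52 ± 0.27 on day 7 and 3.83 ± 0.30 on day 14. miR-28-3p was higher by 2.43 ± 0.19, 2.77 ± 0.20 and 2.53 ± 0.23 and miR-363-3p lower, at -1.49 ± 0.26, -1.5 ± 0.26 and -1.57 ± 0.29 on the same days. Day 3 also brought falls in miR-322-5p, at -1.0 ± 0.14, and in miR-150-5p, a lymphocyte miRNA, at -0.96 ± 0.19. On day 7, miR-16-5p fell by 1.49 ± 0.16 and miR-466c-5p by 1.35 ± 0.21 on the log2 scale. On day 14, miR-100-5p fell by 1.29 ± 0.27, miR-130b-3p by 1.14 ± 0.27 and miR-218a-5p by 1.12 ± 0.37. In the edgeR test, 115 miRNAs passed on day 3 (62 higher), 170 on day 7 (79 higher) and 116 on day 14 (72 higher). Without control day 14 replicate 1, the day 14 falls of miR-130b-3p, miR-141-3p and miR-218a-5p no longer passed, with values of -0.78, -0.93 and -1.15. miR-141-3p also missed the threshold without high dose day 14 replicate 3, at -0.94.

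**Figure D2:**
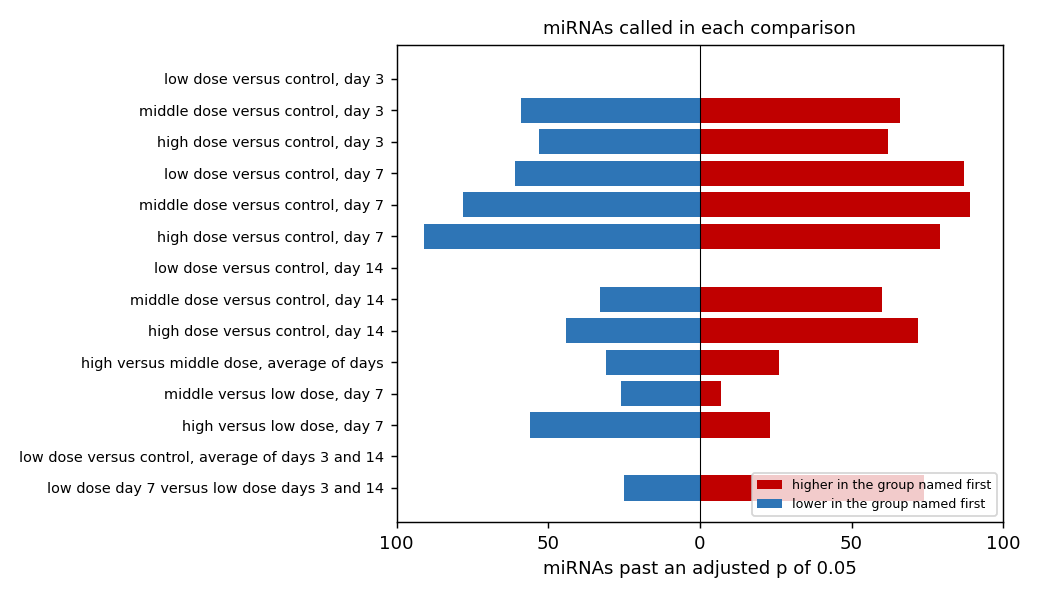
Number of miRNAs past an adjusted p of 0.05 in edgeR's quasi-likelihood test (horizontal axis) in each comparison (vertical axis), with those higher in the group named first to the right of 0 and those lower to the left. The low dose has 0 on days 3 and 14 and 148 on day 7, and the high dose has 115, 170 and 116 on days 3, 7 and 14.

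The 5 miRNAs chosen for the report before the data were examined went in both directions. miR-122-5p, the most hepatocyte-specific miRNA and a serum marker of liver injury, fell at the high dose from 37000 ± 3715 CPM (SD, n = 3) to 24250 ± 1521 on day 3 and from 41570 ± 2700 to 26160 ± 2739 on day 7. Its change averaged over days was -0.51 ± 0.09 (adjusted p = 5.85e-06), and on day 14 it was -0.26 ± 0.16 and did not pass (adjusted p = 0.218). miR-34a-5p, a target of p53, rose 2.13-fold on average, by 1.09 ± 0.19. Its mean level on day 3 was 23.4 ± 5.5 CPM in controls, 22.8 ± 2.8 at the low, 25.3 ± 11.8 at the middle and 53.8 ± 18.5 at the high dose. In the same order miR-34a-5p stood at 21.5 ± 4.5, 28.8 ± 1.5, 25.8 ± 9.9 and 46.1 ± 9.7 on day 7 and at 12.4 ± 3.4 (n = 2), 14.7 ± 3.7, 26.2 ± 5.2 and 24.9 ± 6.7 on day 14. miR-331-3p rose 2.45-fold on average, by 1.30 ± 0.17, and stood at 36.4 ± 7.7, 46.3 ± 4.0, 52.6 ± 20.9 and 135.4 ± 16.2 CPM in these groups on day 3. For miR-331-3p the means were 46.2 ± 11.8, 49.5 ± 7.3, 68.1 ± 8.4 and 90.3 ± 21.4 on day 7 and 37.7 ± 4.9 (n = 2), 47.1 ± 4.2, 88.4 ± 30.4 and 76.7 ± 33.1 on day 14. miR-21-5p, an abundant miRNA tied to inflammation and fibrosis, fell by 0.53 ± 0.11 and miR-192-5p, another liver-enriched miRNA, by 0.19 ± 0.06 on the log2 scale. The call for miR-192-5p ended with no low-count filter, at -0.12, and without day 7, at -0.13.

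Lists of related miRNAs fixed in advance were counted in the high dose average. Of the 9 let-7 family members, which restrain proliferation, 7 fell and 0 rose, among them let-7c-5p at -0.75 ± 0.09, let-7b-5p at -0.75 ± 0.10, let-7d-5p at -0.44 ± 0.07 and let-7a-5p at -0.46 ± 0.08. As a set the let-7 family was lower on day 3 in camera (adjusted p = 0.0159) but not with an estimated correlation (adjusted p = 0.885). In the average it did not pass camera (adjusted p = 0.116). No other list passed camera in a comparison of the high dose with control. In fry, which does not compare a list with the other miRNAs, let-7 passed on day 3 (adjusted p = 0.000607), on day 7 (0.000114) and in the average (8.23e-06). The hepatocyte list passed fry on day 14 (0.00429) and in the average (0.00128), where its camera values were 0.776 and 0.999. Of 14 hepatocyte-abundant miRNAs, 7 rose, with miR-148a-5p at 1.72 ± 0.13 and miR-148a-3p at 0.72 ± 0.09, and 5 fell, with miR-122-3p at -0.67 ± 0.10 and miR-194-5p at -0.57 ± 0.07. Of 4 members of the miR-34 and miR-215 list, miR-34a-5p rose and miR-34c-5p fell, at -0.65 ± 0.16, while miR-34c-3p (-0.95 ± 0.51) and miR-34b-5p (0.15 ± 0.29) did not pass. miR-34c-3p passed without control day 3 replicate 3 (-1.14) or high dose day 7 replicate 2 (-1.34). In the sterol-linked list of 5, miR-182 rose by 0.78 ± 0.13, and both arms of miR-33, which lies within the gene of the sterol regulator Srebf2, fell: miR-33-5p by 0.41 ± 0.10 and miR-33-3p by 0.49 ± 0.12. Without day 7, miR-33-5p was at -0.30 and not called. The inflammation-linked list of 9 had 2 higher, with miR-146b-5p at 0.50 ± 0.16, and 4 lower, with miR-212-5p at -1.08 ± 0.38 and miR-21-3p at -0.34 ± 0.13. These 3 calls were lost without day 7, at 0.36, -0.86 and -0.36. That of miR-212-5p was also lost after thinning to one depth (-0.82), and that of miR-21-3p with no low-count filter (-0.26) and without high dose day 14 replicate 3 (-0.25). Of 18 members of the miR-17/92 cluster and its paralogs, 5 rose, including miR-92b-3p at 2.23 ± 0.19 and miR-92a-3p at 1.06 ± 0.10, and 5 fell, including miR-25-3p at -0.54 ± 0.09. Of 5 miR-29 members, 2 rose, miR-29c-3p at 0.40 ± 0.11 and miR-29a-5p at 0.39 ± 0.13, and miR-29b-3p fell, at -0.57 ± 0.10. miR-29c-3p was not called without day 7 (0.31) or control day 14 replicate 1 (0.28), nor miR-29a-5p with library size alone (0.31). Of 10 tested members of the Dlk1-Dio3 imprinted cluster, miR-434-3p rose by 1.12 ± 0.33 and no other member passed. Of the hypoxia-linked miR-210 hairpin, the scarce miR-210-5p (mean 7.2 CPM) fell by 1.26 ± 0.17. The more abundant miR-210-3p (171.1 CPM), at 0.04 ± 0.09, did not pass. Adjusted over the list alone, the counts were the same for let-7 (7 lower) and for the hepatocyte list (7 higher and 5 lower). Fewer passed over the list alone among white and red blood cell markers, where 0 and 0 were higher against 1 and 1 over all miRNAs.

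Markers of other cell types in the liver moved in different directions in the same comparison. Both tested endothelial miRNAs fell, miR-126a-3p at -0.76 ± 0.09 and miR-126a-5p at -0.52 ± 0.06. Of 7 white blood cell markers, miR-150-5p fell by 0.58 ± 0.11 and miR-142-3p by 0.54 ± 0.13 on the log2 scale, and miR-342-3p was higher by 0.37 ± 0.15, a call that was lost under several settings, down to 0.10 without day 7. miR-342-5p, at -0.78 ± 0.35, did not pass, but it did with library size alone (-0.85) and without any of 6 single libraries (-1.13 to -0.84). These were control day 3 replicate 1, control day 7 replicates 1 and 2, and high dose day 3 replicate 2, day 7 replicate 1 and day 14 replicate 1. Of 7 stellate and smooth muscle markers, miR-145-5p rose by 2.03 ± 0.15 and miR-143-3p by 0.32 ± 0.07, and 3 fell, miR-145-3p, miR-143-5p and miR-214-3p. Of 4 red blood cell markers, miR-144-3p fell by 0.91 ± 0.19 and miR-486 was higher by 0.47 ± 0.20. The miR-486 call was lost with library size alone (0.38), no low-count filter (0.53) and the stricter filter (0.42). It was also lost after thinning (0.44), without day 7 (0.39) and when single libraries were left out (down to 0.36). In the miR-200 family of bile duct and other epithelia, with 7 members tested, miR-141-3p fell and miR-200a-3p fell by 0.56 ± 0.12 while miR-429 rose by 0.54 ± 0.17. Of 2 muscle markers miR-499-5p rose by 0.50 ± 0.16, though it was not called without day 7 (0.41), and the pancreas marker miR-375-3p, at 0.11 ± 0.14, did not pass. Other list members the rule selects did not pass either: miR-200c-3p (-0.41 ± 0.23), miR-144-5p (0.34 ± 0.19), miR-451-5p (-0.16 ± 0.19) and miR-133a-3p (0.54 ± 0.37). miR-200c-3p passed without high dose day 3 replicate 3 (-0.56), miR-144-5p without control day 7 replicate 1 (0.46) and miR-133a-3p without control day 3 replicate 3 (0.96) or control day 14 replicate 1 (0.99).

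The arms of single hairpins often went opposite ways. A miRNA hairpin yields a 5p and a 3p product. In the high dose average, 42 hairpins had both arms past the threshold, and in 18 of them (42.9%, exact 95% interval 27.7 to 59%) one arm rose and the other fell. miR-322-3p rose by 2.82 while miR-322-5p fell by 0.86 ± 0.08. miR-191a-5p rose while miR-191a-3p fell by 0.37 ± 0.11. miR-28-3p rose while miR-28-5p fell by 0.25 ± 0.07, and miR-99a-5p fell while miR-99a-3p rose by 1.01 ± 0.13 on the log2 scale. In the low dose on day 7 against control, 2 of 18 such hairpins (11.1%, interval 1.4 to 34.7%) were opposite. Whether these shares differ was not tested.

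**Figure D3:**
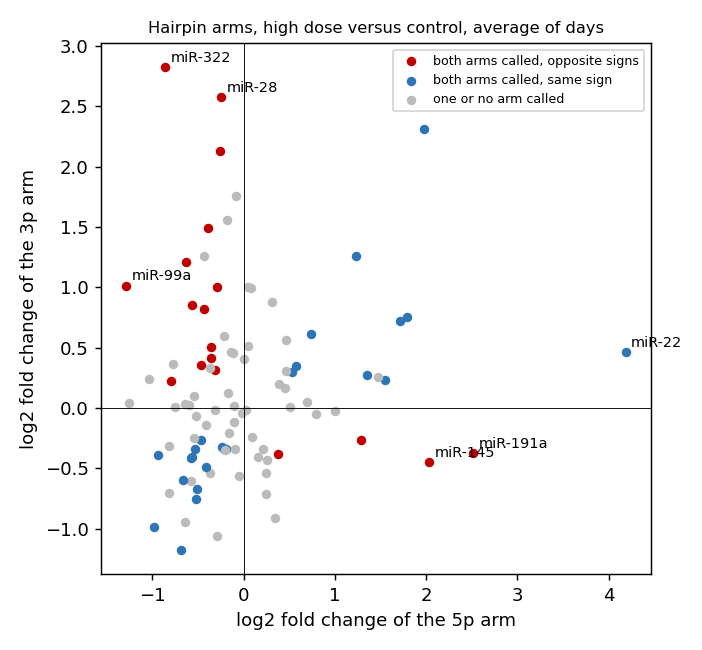
Log2 fold change of the 5p arm (horizontal axis) against that of the 3p arm (vertical axis) of 96 hairpins in the high dose average against control, one point per hairpin. Both arms passed the threshold in 42, of which 18 (red) had opposite signs and 24 (blue) the same sign.

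At the middle dose, averaged over days, miR-128-3p rose by 3.93 ± 0.23, miR-22-5p by 3.83 ± 0.16, miR-671 by 3.28 ± 0.19 and miR-322-3p by 2.95 ± 0.13. miR-363-3p, miR-16-5p, miR-466b-5p and miR-15b-5p changed by -1.43 ± 0.15, -0.98 ± 0.09, -0.97 ± 0.21 and -0.93 ± 0.11. The rule also named miR-222-3p on day 7, at 3.37 ± 0.31, and miR-130b-3p on day 14, at -1.16 ± 0.26. Without control day 14 replicate 1, miR-130b-3p was at -0.76. Differences between days were not tested at the middle dose. In the edgeR test, 125 miRNAs passed on day 3 (66 higher), 167 on day 7 (89 higher), 93 on day 14 (60 higher) and 203 in the average (105 higher). With library size alone as scaling, the share of higher miRNAs among the calls moved from 52.8% to 38.7% on day 3, from 64.5% to 37.9% on day 14 and from 51.7% to 41.3% in the average. Under that scaling the high dose on day 14 moved from 62.1% to 41.3%.

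The low dose differed from control on day 7 and not detectably on days 3 and 14. On day 7, miR-22-5p was higher by 3.97 ± 0.26, miR-128-3p by 3.60 ± 0.37, miR-145-5p by 3.55 ± 0.25 and miR-191a-5p by 3.20 ± 0.19, while miR-411-5p, miR-598-3p and miR-363-3p were lower, at -1.95 ± 0.49, -1.25 ± 0.31 and -1.23 ± 0.25. miR-136-3p, at -1.25 ± 0.51, was no longer called with no low-count filter (-1.26) or without any of 4 single libraries, the low dose replicates 2 and 3 and the control replicates 2 and 3 (-1.21 to -1.01). In edgeR, 148 miRNAs passed on day 7, 87 higher and 61 lower. On day 3, 0 passed in edgeR and 0 in DESeq2, with 25 at an unadjusted p under 0.05 in edgeR; the smallest p values belonged to miR-871-3p at -6.05 ± 1.53, miR-3473 at 0.90 ± 0.28 and miR-150-5p at -0.59 ± 0.19. Without control day 3 replicate 1, 2 passed, miR-871-3p at -6.64 and miR-150-5p at -0.79. On day 14, 0 passed in edgeR and 0 in DESeq2, with 11 at an unadjusted p under 0.05, led by miR-455-3p at -1.15 ± 0.41, miR-142-5p at -0.61 ± 0.23 and miR-30b-3p at 0.64 ± 0.25. The average over days called 74, 54 of them higher, with miR-152-5p at 0.60 ± 0.12, miR-30d-3p at 0.53 ± 0.10 and miR-98-5p at -0.29 ± 0.08. Without day 7 the average called 0 in edgeR and 0 in DESeq2, with 16 at an unadjusted p under 0.05. The average over days 3 and 14 alone called 3 without control day 14 replicate 2. Without control day 7 replicate 1 the average over all days called 115. With DESeq2's size factors the higher share in that average was 59.3% in place of 73%.

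The difference between days at the low dose was itself tested, in comparisons added after the data were examined. The low dose effect was larger on day 7 than on day 3 for miR-145-5p, by 3.81 ± 0.34, miR-22-5p, by 3.57 ± 0.37, miR-191a-5p, by 3.15 ± 0.25, and miR-322-3p, by 2.95 ± 0.28, and 106 miRNAs passed in edgeR, 71 of them more positive on day 7. Against day 14 it was 109, 70 of them more positive on day 7, with miR-22-5p at 4.02 ± 0.38, miR-365-3p at 3.55 ± 0.43 and miR-200b-3p at -1.60 ± 0.34. Low dose day 7 against low dose days 3 and 14, with no control library involved, called 99 miRNAs, 74 higher, with miR-22-5p at 3.24 ± 0.19, miR-191a-5p at 2.81 ± 0.15 and miR-145-5p at 2.75 ± 0.19. Control levels of miR-145-5p also differed, at -0.99 ± 0.24 for day 7 against day 3, which adds to its difference of 3.81. With DESeq2's size factors 52.3% of the calls in that last comparison were higher, in place of 74.7%, and the median of all miRNAs shifted by -0.15. With the same factors the more positive share was 52.8% in place of 67% for day 7 minus day 3 and 55.9% in place of 64.2% for day 7 minus day 14.

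Across all 4 dose levels, the trend per dose step was steepest upward for miR-22-5p (1.5 ± 0.05), miR-128-3p (1.42 ± 0.07), miR-671 (1.12 ± 0.06) and miR-322-3p (1.03 ± 0.04), and downward for miR-363-3p (-0.53 ± 0.05), miR-24-2-5p (-0.43 ± 0.03), miR-141-3p (-0.42 ± 0.06) and miR-99a-5p (-0.39 ± 0.04), among the miRNAs the rule selects. A positive slope does not mean an even climb. miR-22-5p stood at 11.4 ± 1.9 CPM in controls, 15.1 ± 3.4 at the low, 148.1 ± 33.9 at the middle and 211.0 ± 11 at the high dose on day 3, but at 9.24 ± 3.97, 149.0 ± 16.4, 188.9 ± 58.6 and 218.9 ± 7.3 on day 7. miR-322-3p stood at 21.2 ± 7.6, 23.2 ± 4.5, 151.6 ± 21.8 and 118.1 ± 1.7 CPM on day 3. In edgeR, 214 miRNAs had a slope past the threshold, 105 upward and 109 downward.

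**Figure D4:**
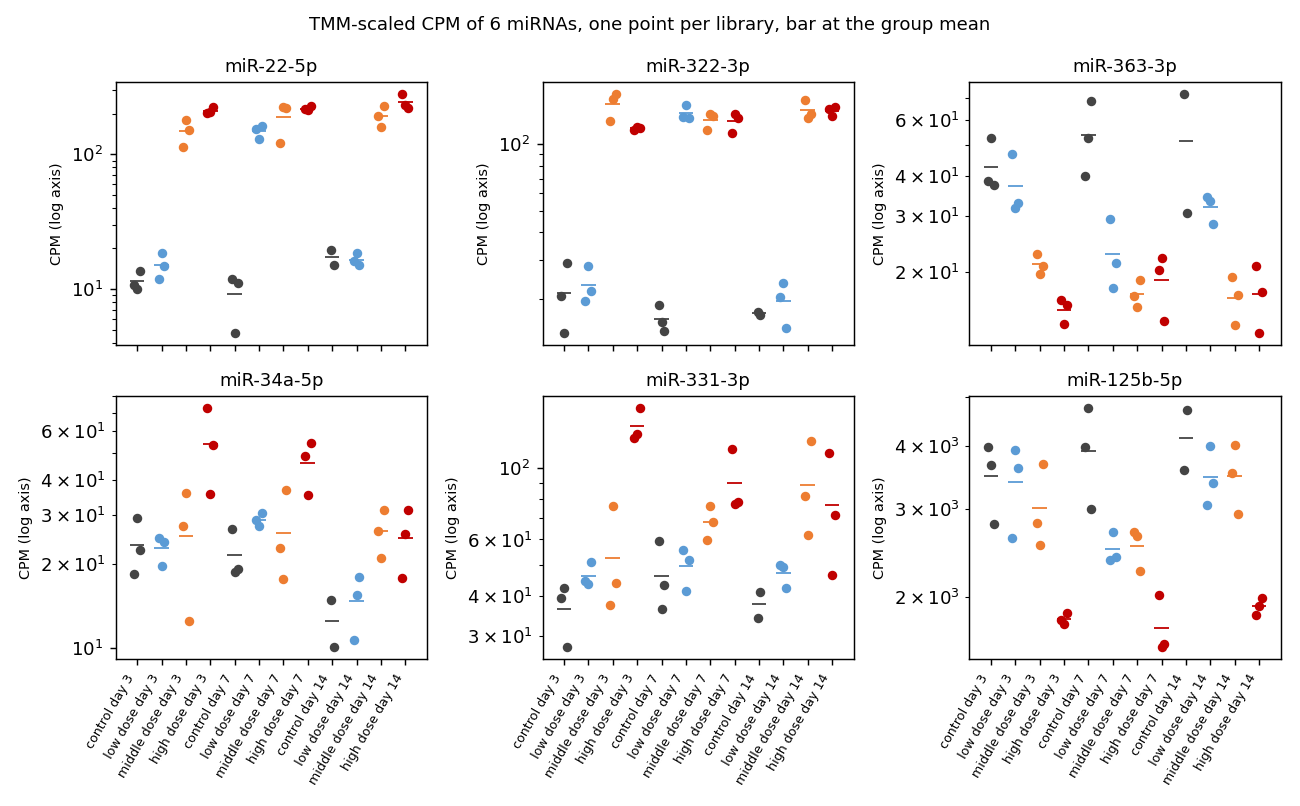
TMM-scaled CPM (vertical log axes) of 6 miRNAs in each library (points) by group (horizontal axis), with a bar at the group mean. On day 3, miR-22-5p means run 11.4, 15.1, 148.1 and 211.0 and miR-34a-5p means 23.4, 22.8, 25.3 and 53.8 CPM for control, low, middle and high dose.

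The high dose effect did not differ detectably between days. No miRNA passed for day 7 minus day 3 in edgeR (0, against 36 at an unadjusted p under 0.05, and 0 in DESeq2), where the smallest p values were those of miR-421-3p at -0.86 ± 0.23, miR-182 at 1.10 ± 0.30 and miR-210-5p at -1.39 ± 0.39. Without control day 7 replicate 1, 19 passed, including miR-182 at 1.22 and miR-210-5p at -1.39. For day 14 minus day 3 the count was 0 in edgeR and 0 in DESeq2, with 24 at an unadjusted p under 0.05, led by miR-182 at 1.03 ± 0.32, miR-582-3p at -2.11 ± 0.70 and miR-18a-3p at -3.02 ± 1.03. The 3 days share no library, but each of these comparisons crosses the gap between the 2 clusters. Agreement between days therefore cannot tell a dose effect from another difference between the clusters. Across the 328 miRNAs, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.757 between days 3 and 7 (Spearman's rho 0.793), 0.657 between days 3 and 14 (rho 0.755) and 0.806 between days 7 and 14 (rho 0.765). With no low-count filter these Pearson values were 0.367, 0.342 and 0.324, and with the stricter filter 0.879, 0.879 and 0.908. Of the 115 miRNAs called on day 3, 112 had the same sign on day 7 and 110 on day 14. The high dose on day 3 also correlated with the low dose on day 7, at r = 0.579 (rho 0.557), and 102 of those 115 miRNAs shared its sign. That low dose comparison crosses the gap as well. For the low dose on days 3 and 14, which lies with the controls, r with the high dose of another day was between 0.052 and 0.285.

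Controls of different days were compared as well. miR-182 and miR-145-5p were lower on day 7 than on day 3, at -1.04 ± 0.21 and -0.99 ± 0.24, and miR-181a-2-3p, miR-15a-5p and miR-16-5p were higher, at 0.73 ± 0.19, 0.61 ± 0.15 and 0.59 ± 0.16. These were the 5 calls of edgeR, with 71 at an unadjusted p under 0.05, and DESeq2 called 22. With only the libraries of the days compared, or with no low-count filter, edgeR called 1, since miR-182 alone passed. Without control day 7 replicate 1 there were 62, without replicate 2 or 3 of that group 1 each, and without control day 3 replicates 1 and 3 in turn 3 and 2. Day 14 against day 3 gave 0 in edgeR and 0 in DESeq2, with 29 at an unadjusted p under 0.05, led by miR-335 at -0.75 ± 0.22, miR-15b-5p at -0.72 ± 0.21 and miR-411-5p at -2.0 ± 0.58, and 1 passed without control day 3 replicate 1.

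Comparisons among dosed groups that lie on one side of the gap were added after the data were examined. Between the high and middle doses, averaged over days, miR-125b-5p was lower at the high dose by a log2 change of -0.72 ± 0.10, miR-99a-5p by -0.73 ± 0.12, miR-145-3p by -0.65 ± 0.11, miR-125a-5p by -0.57 ± 0.12 and miR-221-5p by -1.16 ± 0.29. miR-598-3p was higher by 0.68 ± 0.17, miR-802-3p by 0.67 ± 0.13, miR-340-5p by 0.50 ± 0.10 and miR-107-3p by 0.48 ± 0.08. miR-331-3p was higher by 0.52 ± 0.15 (adjusted p = 0.0168) and miR-34a-5p by 0.61 ± 0.18 (adjusted p = 0.0151). On day 14 alone the mean levels at the high and middle doses were 76.7 and 88.4 CPM for miR-331-3p and 24.9 and 26.2 for miR-34a-5p, and the difference was not tested by day. The call for miR-331-3p was lost without high dose day 14 replicate 1, at 0.43, and those for miR-34a-5p and miR-221-5p without day 7, at 0.50 and -0.95. miR-122-5p, at -0.17 ± 0.08 (adjusted p = 0.142), did not pass, but it did without middle dose day 3 replicate 2, at -0.25. In edgeR 57 miRNAs passed, 26 higher and 31 lower, and without day 7 there were 30. With library size alone the higher share was 68.1% in place of 45.6%. Of the 206 miRNAs called in the high dose average against control, 30 were also called with the same sign between high and middle dose and 7 with the opposite sign. These comparisons share the high dose libraries. White blood cell and stellate markers passed fry here (adjusted p = 0.0228 for each) but not camera (0.121 and 0.28).

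On day 7, where all 3 doses lie on one side, miR-193a-3p was lower at the high than at the low dose by a log2 change of -1.41 ± 0.21, miR-374-5p by -1.28 ± 0.20, miR-24-2-5p by -1.10 ± 0.18 and miR-322-5p by -0.95 ± 0.14. miR-598-3p, miR-532-5p and miR-340-5p were higher by 1.18 ± 0.30, 0.89 ± 0.20 and 0.79 ± 0.17. miR-331-3p was higher by 0.87 ± 0.27 but was not called without low dose day 7 replicate 2 or high dose day 7 replicate 1, at 0.75 and 0.66. Of 7 white blood cell markers 4 were lower, led by miR-150-5p at -1.23 ± 0.19, miR-342-3p at -1.14 ± 0.25 and miR-142-5p at -0.96 ± 0.21. Without high dose day 7 replicate 3, miR-142-5p was at -0.68 and not called. The list passed camera (adjusted p = 0.0238) but not with an estimated correlation (adjusted p = 0.654). In fry it passed (0.000345), as did the miR-29 family (0.00792), whose camera value was 0.37. In edgeR 79 miRNAs passed, 23 higher and 56 lower, and 49 passed without high dose day 7 replicate 3. With DESeq2's size factors the median of all miRNAs shifted by 0.16 and the higher share was 54% in place of 29.1%. Between the middle and low doses 33 passed, 7 higher and 26 lower, with miR-193a-3p at -1.30 ± 0.21, miR-150-5p at -0.86 ± 0.19 and miR-182 at 0.99 ± 0.21. Without middle dose day 7 replicate 3 it was 13 and miR-150-5p, at -0.69, was not called. It was 20 without middle replicate 2 and 21 without low replicate 3. The higher share there was 48.6% with DESeq2's size factors in place of 21.2%.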

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

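The tests of explanations in this part were chosen after the results were seen; the counts over other splits were planned for the planned comparisons and not for the added ones, and the bound that reads them was written after the first counts were seen. The low dose effect differed between days in tests of the difference itself: 106 miRNAs were called for day 7 minus day 3 and 109 for day 7 minus day 14. Among the miRNAs the naming rule selects, the largest differences were those of miR-145-5p, miR-22-5p and miR-191a-5p in the first and of miR-22-5p, miR-365-3p and miR-145-5p in the second. Leaving out single libraries gave 80 to 128 and 82 to 127 calls. For day 7 minus day 3, 8 of 100 splits of dose labels within days gave 106 or more, the highest other 145, so this count does not exclude chance. It does not support chance either: all 8 are among the 10 splits that keep the day 7 groups, which leave the day 7 difference in place, and the other 90 called at most 4. For day 7 minus day 14, 4 of 100 splits gave 109 or more, the highest other 115, a share just under the bound of 0.05. Chance is still not called excluded, since the comparison was added after the data were examined. Its low dose groups lie on opposite sides of the gap, so its count repeats that observation. All 4 are among the 9 that keep the day 7 groups, and the other 91 called at most 1, so this count reads like the previous one.

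The difference belongs to a wider pattern, the 2 clusters of libraries on the first component. As the whole account, with the labels as given, a response to dose that is the same on every day is argued against, since the low dose lies on both sides of the gap. The 99 miRNAs called between low dose day 7 and low dose days 3 and 14 restate that split. Such a response beside 2 sets of libraries was not tested. Exchanged labels do not rescue it, because it would put all libraries of a dose on one side. The controls number 8 and each dose has 3 groups of 3 libraries. No exchange of labels can therefore put whole doses on one side with 14 and 21 libraries on the 2 sides. Sequencing depth is argued against too as the account of the calls of the high dose average, which crosses the gap. Of its 206 calls, 193 were also called after all libraries were thinned to 2665943 counts. The first component was not computed again after thinning. Libraries made, sequenced or counted in 2 sets cannot be told apart from an effect of treatment, because 0 of the 12 groups have libraries on both sides of the gap. An effect of the low dose that is present on day 7 and wanes by day 14 also stays open. So does an exchange of labels among whole groups beside a response that differs between days. Neither was tested.

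Other splits of the same samples were counted for each comparison except those that set control day 14, with its 2 samples, against 1 other group. For the high dose average 1 of 100 splits, the real one, gave its 206 calls and the highest other gave 147; for the middle dose average it was 1 of 100, with 203 and 154; for the trend 1 of 100, with 214 and 73; and for the high against the middle dose, a comparison added after the data were examined, 1 of 100, with 57 and 25. Chance is excluded for the high and middle dose averages and the trend as an account of the count, but not a structure of the samples that follows the groups. For the high against the middle dose chance is not called excluded, since that comparison was added after the data were examined. For low dose day 7 against low dose days 3 and 14 it was 1 of 84, with 99 and 65. That comparison was added because these groups lie on opposite sides of the gap, so its count repeats that observation and is no separate evidence against chance. For the low dose average 7 of 100 splits reached 74, the highest other 97, which does not exclude chance and does not support it. All 7 are among the 12 that keep the day 7 groups, and the other 88 called at most 1. With 3 samples against 3 the 10 splits cannot give a share under 0.05. There the real and highest other counts were 125 and 4 for the middle and 115 and 1 for the high dose on day 3, and 148 and 2, 167 and 22, and 170 and 9 for the low, middle and high dose on day 7. Among dosed groups on day 7 they were 79 and 0 for high against low and 33 and 0 for middle against low. For control day 7 against day 3 they were 5 and 48, with 3 splits as large. For the comparisons with 0 calls every split is as large by definition, so these shares say nothing about chance. They were 10 of 10 for the low dose on day 3 (highest other 13), 100 of 100 for the low dose over days 3 and 14 (highest other 8) and 100 of 100 for the high dose effect on day 14 minus day 3 and on day 7 minus day 3. In these last 2 the highest other splits called 131 and 154, the second being 119 among splits that move the day 7 groups. A split that mixes the groups of one day leaves the difference between the high dose and control of the other day in the count. On every day the high dose and the controls lie on opposite sides of the gap. These counts therefore cannot tell the dose groups within days from the 2 clusters.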

How the results depend on the processing

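The alternatives were chosen before the data were examined, except thinning to one depth, either run alone, the averages without day 7 and all alternatives for the 7 added comparisons. Summing rows of one mature miRNA did not apply, since no name repeats, and using only the days compared does not apply to averages over all days. The counts for the middle and high doses against control, on each day and averaged, and for the trend stayed within 1.5 times of their values under every alternative run. Control day 7 against day 3, with 5 calls, gave 3 with DESeq2's size factors, 3 with the stricter filter, 3 after thinning, 1 with no low-count filter, 1 with only the days compared, 22 in DESeq2 and 1 to 62 with single libraries left out. The cause was not tested. Its count under the replicate block was 0; the block moved no other count by over 1.5 times (high dose average 205). Of 268 named values it left 260 on their side of the threshold and ended 8 calls: those 5, miR-136-3p at the low dose on day 7 (-1.12), miR-486 in the high dose average and miR-127-3p between low dose day 7 and low dose days 3 and 14. The replicate numbers share only a number: 14 of 51 pairs with the same number had a correlation of deviations over 0.1, the median was -0.01 and 9 of 35 samples correlated best with their own number. Without day 7 the low dose average called 0 in place of 74. The low dose had 148 calls on day 7 alone and 0 on day 3 and on day 14. The high against the middle dose called 30 in place of 57 without day 7. Fewer libraries entered both averages. With no low-count filter, which tests 612 miRNAs, high against low dose on day 7 called 45 in place of 79 and middle against low 20 in place of 33; the latter was 19 with only the day 7 libraries. Leaving out single libraries gave 0 to 2 calls for the low dose on day 3, 53 to 115 for its average, 0 to 19 for the high dose effect on day 7 minus day 3, 0 to 1 for control day 14 against day 3, 0 to 3 for the low dose over days 3 and 14, 49 to 67 for high against low dose on day 7 and 13 to 41 for middle against low; the lowest, 13, came without middle dose day 7 replicate 3, which together with middle replicate 2 (20) and low replicate 3 (21) decides that count. The correlations of high dose effects depend on the filter: 0.367, 0.342 and 0.324 with none and 0.879, 0.879 and 0.908 with the stricter one, for days 3 and 7, 3 and 14, and 7 and 14. Why these correlations differ between filters was not tested. Where a single control is left on day 14, it is assumed to vary like the other groups. No named miRNA that passed changed sign. Among named values, DESeq2 kept 267 of 267 on their side of the threshold and thinning 259 of 264; leaving out single libraries kept 3082 of 3187.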

Other observations

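The tests of explanations in this part were chosen after the results were seen. Between the high and the middle dose, miR-100-5p changed by -0.53 ± 0.14, miR-99b-5p by -0.42 ± 0.10 and let-7e-5p by -0.26 ± 0.08, beside the falls of miR-99a-5p, miR-125b-5p and miR-125a-5p; all 6 passed the edgeR threshold. let-7c-5p, at -0.25 ± 0.09, did not (adjusted p = 0.0543). Against control the 6 did not go one way: at the high dose miR-125a-5p was higher, by 0.50 ± 0.13, miR-99b-5p did not pass, at -0.11 ± 0.10, and the other 4 were lower. As a list, let-7 had 1 of 9 members lower and 0 higher and did not pass camera (adjusted p = 0.28), and no set test was run for the miR-99 and miR-125 families. Members of a family have similar sequences, so their counts may be partly shared. The level of miR-125b-5p at the high dose was 1805 ± 48, 1737 ± 240 and 1915 ± 78 CPM on days 3, 7 and 14, against 3011 ± 601, 2528 ± 240 and 3491 ± 545 at the middle dose. This set was chosen after its values were seen. A smaller share of all cells other than hepatocytes, as the whole cause for miR-125b-5p, miR-99a-5p and miR-100-5p, is argued against: 20 markers of white blood cells, red blood cells, endothelial and stellate cells had a median log2 change of -0.217 (SD 0.206), against -0.531 for the smallest fall of the 3. With 4 of the 20 markers called lower and 0 higher, a smaller contribution stays open. So does a smaller share of, or a change within, 1 cell type: the stellate marker miR-145-3p, at -0.65, lay within the range of the 3. It is 1 of 7 tested stellate and smooth muscle markers, whose median was -0.131, with 2 called lower and 0 higher. As a list these markers fell less than the 3 miRNAs. Whether the markers are absent from hepatocytes was not measured.

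miR-193a-3p stood at a mean of 4054 ± 458 CPM at the low dose on day 7. Its 6 group means at the middle and high doses lay between 1431 and 1678 CPM, and the 5 of the controls and of the low dose on days 3 and 14 between 705.7 and 960.

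The opposite arms of 42.9% of hairpins with both arms called argue against a change in the amount of the hairpin alone as the whole cause in these 42 hairpins as a set. Low counts of one arm are also argued against, since 15 of the 18 had both arms at a mean CPM of at least 10. What stays open is arm-specific processing or stability of the miRNAs, or a difference in ligation, read trimming or counting between the clusters of libraries, which could favour one arm. The share at the middle dose was 31.6% (12 of 38, exact 95% interval 17.5 to 48.7%). In low dose day 7 against low dose days 3 and 14 it was 0 of 10, which allows up to 30.8%. All shares were computed with TMM scaling and not again under another scaling. In the comparison within the low dose, DESeq2's size factors shifted the median of all miRNAs by -0.15, which can change the sign of small changes.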
